A study of Mus musculus with 5 samples.

How the data were processed

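Single-nucleus RNA libraries of mouse hippocampus were analysed from 5 samples in 3 groups, taken from the sample titles: ALPL inhibitor (replicates 1 and 2), GPLD1 (replicates 1 and 2) and mutant GPLD1 (1 library). The deposited values are raw UMI counts per gene and barcode, in 1 matrix per sample with 32285 genes and barcodes already called as nuclei by the authors. Sorting of nuclei and the 10x Genomics 3' chemistry are stated per the labels' protocols. Reads were demultiplexed with bcl2fastq and counted with Cell Ranger against mm10, per the submitters' processing notes; versions, the annotation, the treatment of intronic reads and the sorting gate are not given in the sources used here. A count that leaves out intronic reads lowers the depth of nuclei, and whether it did so here is open. Gene positions were taken from GENCODE M21, on GRCm38, the assembly behind mm10.

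Barcodes with at least 500 UMIs and at most 5% mitochondrial UMIs were kept, which removed 1 of 54597. Doublets were scored with Scrublet as built into scanpy, at an assumed rate of 0.008 per 1000 barcodes of a library, and 2413 predicted doublets were removed (982, 102, 193, 618 and 518 in ALPL inhibitor 1 and 2, GPLD1 1 and 2 and mutant GPLD1, or 7.13%, 1.45%, 2.93%, 4.05% and 4.35%). Counts per nucleus were scaled and log transformed, 2000 variable genes and 40 principal components were used with 15 nearest neighbours, and Leiden clustering at resolution 1 gave 30 clusters. A cluster took the name of a class from markers fixed before the data were examined where at least 3 of them were detected and no other class had more markers among its top 10 genes by fold. Further limits were set after the data were seen. A cluster with none of its own markers in its top 10 needed 5 detected markers, and clusters with a median doublet score above 0.2 or with over 60% of their nuclei, at equal library sizes, from 1 library stayed unnamed. A stricter earlier limit had left 1 of the oligodendrocyte-like clusters unnamed. Clusters with markers of astrocytes, fibroblasts, mural or endothelial cells were clustered again, and parts that met the same rules for one of these 4 classes took its name. Other parts stayed unnamed, among them 268 and 128 nuclei of low depth that met the rules for inhibitory neurons. Unnamed nuclei were 3167 (6.07%), at 7.88%, 2.79%, 2.98%, 5.88% and 8.01% of the libraries in the order above. Deposited annotations of cell types were not used here.

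Counts were summed per library and class, since nuclei are not replicates, and 10 classes with at least 10 nuclei in every library were tested. Lowest and highest totals per library ranged from 61262 and 179706 UMIs in Cajal-Retzius-like nuclei to 11857840 and 21028805 in CA1-like nuclei. Each class was fitted with edgeR's quasi-likelihood test on all 5 libraries with TMM normalization and filterByExpr, and p-values were adjusted by Benjamini-Hochberg over genes within a class and comparison at a threshold of 0.05. The median log2 fold change over all genes of a class was 0.027 or less in size in every comparison. The single mutant library gives no spread of its own, so it is assumed to vary as the other groups do. CPM values of tested genes are TMM-scaled, while CPM of Gpld1 and Alpl, and those of Ttr and AC149090.1 given across classes, are scaled to the UMIs of the nuclei named alone. The biological coefficient of variation was 8.98% in CA1-like to 22.9% in Cajal-Retzius-like nuclei. Numbers of nuclei per class were tested with edgeR's quasi-likelihood test with the library total as offset. Intervals of shares are exact binomial and those of counts exact Poisson at 95%, and cover counting error only. Libraries of the same group differed by more than sampling noise in every class (chi-square per gene of 1.44 to 8.60), so all were used as separate libraries.

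Gene lists for the tissue and treatments were fixed before the data were examined, 34 in all. Of these, 13 applied only to endothelial, mural or astrocyte nuclei, which had no testable class, and gave no value. The other 21 were tested in the classes named for them in advance with camera at a preset correlation of 0.01, where at least 5 members were measured, and adjusted over the 131 tests of list and class in a comparison. Some list members, such as Clec7a, Mx1 and Bmal1, had no matching symbol in the matrices. A group at 0 UMIs was given a floor of 3 counts over the group. Genes to name were chosen by a rule fixed in advance: Gpld1 and Alpl; up to 2 higher and 2 lower genes per class past the threshold whose libraries do not overlap (6 and 6 in endothelial-like nuclei); up to 4 members with the smallest p of each list past the threshold; the 2 genes with the smallest p of a class with no call; at most 30 per comparison, with predicted genes counted but not named. The rule gave more than 30 genes, so which lists and classes are given members was decided after the values were seen, with members in order of p. Galntl6 and Ttr, whose libraries overlap, and AC149090.1 and Cxcl10, where followed across classes, were chosen after their values were seen. Some genes that the rule gives are not reported here.

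The scripts were tested on simulated counts drawn from the means and library sizes of these data, with 200 changed genes per class and comparison. Genes changed 2-fold were recovered in 1% (microglia-like) to 62% (dentate granule neuron-like) of cases for GPLD1 against mutant GPLD1, and genes changed 4-fold in 42% to 89%. For the inhibitor against mutant GPLD1 these ranges were 2% to 58% and 26% to 86%, and for GPLD1 against the inhibitor 10% to 68% and 62% to 90%. Unchanged genes called per class numbered up to 28, 16 and 23 in these comparisons. The 28, in dentate granule neuron-like nuclei, stood beside 62 and 87 recovered genes, a larger share of false calls than the threshold of 0.05 allows. Most classes and comparisons exceeded that share. For GPLD1 against mutant GPLD1, subicular or cortical nuclei had 23 beside 47 and 85, and oligodendrocyte-like nuclei 14 beside 18 and 68. Cajal-Retzius-like nuclei had 0 there. Lists raised 1.5-fold were called in 10, 8 and 10 of 10 cases, and unchanged lists in 0 of 120, 0 of 118 and 1 of 119. Each gene was drawn independently, so simulated lists held no correlation between genes and no deviation of a whole library. The low rate of false list calls therefore does not carry over to the real libraries.

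Alternatives fixed in advance were RLE size factors, DESeq2, no filter on low counts, a fit on only the groups compared, the replicate number as a block, each library left out, at least 1000 UMIs per nucleus, doublets kept, Leiden resolution 2 (41 clusters), classes thinned to equal UMIs in every library, at least 30 nuclei, camera with an estimated correlation, fry, and TMM over classes for shares. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 (camera and fry), DESeq2 1.42.0, Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. Counts of changed genes in endothelial-like nuclei, and fold changes of Gpld1 and Alpl there, were planned and have no value because that class was too small.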

Results

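Nuclei of the mouse hippocampus were isolated and sorted by flow cytometry, and their RNA was counted with the 10x Genomics 3' assay, which marks each captured molecule with a unique molecular identifier (UMI). The 5 libraries came from aged mice in 3 treatment groups. GPLD1 is a phospholipase that circulates in blood and cuts proteins from their glycosylphosphatidylinositol (GPI) anchor, and 2 libraries came from mice treated with it. Mice of the group with 1 library, taken here as the reference, were treated with a mutant form of GPLD1. Sample titles of both these groups add OE, commonly short for overexpression, and the way GPLD1 was delivered is not given in the sources used here. The remaining 2 libraries came from mice given an inhibitor of ALPL, the tissue-nonspecific alkaline phosphatase (TNAP), which is itself held on cells by a GPI anchor. The series title presents GPLD1 as a liver factor of exercise that acts on the vessels of the brain, so the comparisons ask how hippocampal cells with GPLD1 or the inhibitor differed from those with mutant GPLD1, and how both treatments differed. An experiment in 5xFAD mice, a model of amyloid disease, is also part of the series design and was not analysed here. Nothing in the labels says that the libraries came from separate animals. The p-values of single genes and of shares therefore measure only the spread between these libraries, which may be technical. Camera with a preset correlation compares list genes with other genes at an assumed correlation of 0.01. Its p-values, however small, do not measure how a whole list varies between libraries.

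The matrices held 54597 barcodes and 416186750 UMIs. Total UMIs per library were 100982257 and 55938175 with the ALPL inhibitor (replicates 1 and 2), 53182095 and 111997679 with GPLD1 (replicates 1 and 2), and 94086544 with mutant GPLD1. After filtering, 52183 nuclei remained, with 12800, 6943, 6403, 14645 and 11392 in the same order. Median UMIs per nucleus were 3532 and 2483 with the inhibitor, 5187 and 4194 with GPLD1, and 4669.5 with mutant GPLD1.

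Oligodendrocyte-like nuclei were the largest class and made up 31.4% to 44.0% of a library, followed by dentate granule neuron-like nuclei at 16.1% to 24.8% and CA1 pyramidal neuron-like nuclei at 8.79% to 13%. Microglia-like nuclei made up 6.21% to 11%. Further classes were subicular or cortical excitatory neurons, inhibitory neurons, CA2 or CA3 pyramidal neurons, oligodendrocyte precursors, mossy cells (glutamatergic neurons of the dentate hilus) and Cajal-Retzius cells (reelin-producing neurons of the outermost layer), all named from their markers and so only "-like". Cells of the vessel wall were nearly missing from the sorted nuclei, with 39 endothelial-like nuclei in all (4 and 5 with the inhibitor, 5 and 14 with GPLD1, 11 with mutant GPLD1), 31 mural-like and 46 fibroblast-like nuclei. Astrocyte-like nuclei numbered 69 and border macrophage-like nuclei 118. None of these 5 classes had 10 nuclei in every library, so genes were tested in the other 10 classes, and the vascular response named in the title could not be tested here. No share of a class passed an adjusted p of 0.05 in any comparison (edgeR quasi-likelihood on the numbers of nuclei, Benjamini-Hochberg). At an unadjusted p under 0.05 there were 0 classes for GPLD1 against mutant GPLD1, 2 for the inhibitor against mutant GPLD1 and 1 for GPLD1 against the inhibitor, and no other tool was run on shares. The lowest p belonged to astrocyte-like nuclei, whose share was 0.0781% and 0.0576% with the inhibitor, 0.141% and 0.157% with GPLD1, and 0.202% with mutant GPLD1. Their log2 difference between the inhibitor and mutant GPLD1 was -1.51 (SE 0.33, adjusted p = 0.142), with 4 to 23 nuclei per library. The sorting gate is not given in the sources used here, and both it and the depth gap between libraries can set such shares.

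**Figure D1:**
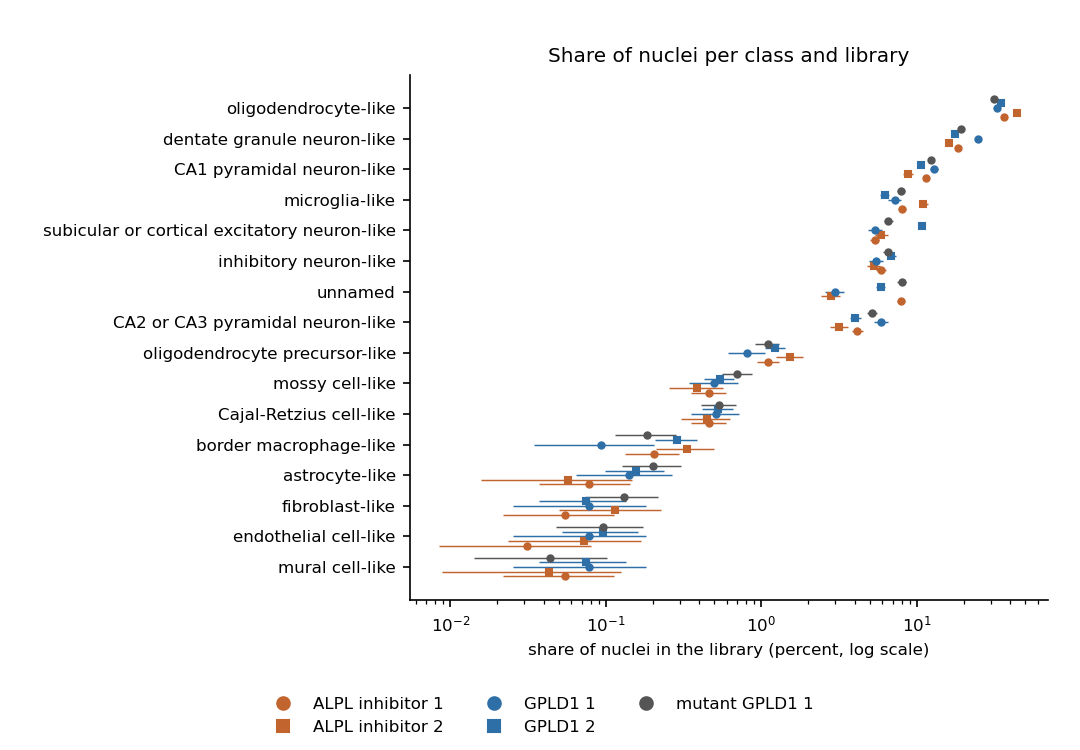
Share of nuclei (percent, log axis) of each class in each of the 5 libraries, with points for libraries and bars for exact binomial 95% intervals that cover counting error only. Oligodendrocyte-like nuclei lie between 31.4% and 44.0%, and endothelial-like nuclei between 0.0313% and 0.0966%.

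Of the genes that the treatments are named for, that of GPLD1 was measured at similar levels in all groups, while that of ALPL was too scarce to compare. Gpld1 (ENSMUSG00000021340, GRCm38 chromosome 13, 24943152 to 24992501, plus strand), the mouse gene of the phospholipase, stood at 18.1 and 16.7 CPM (counts scaled to the total UMIs) over all nuclei with the inhibitor, 15.9 and 16.7 with GPLD1, and 15.9 with mutant GPLD1. Its level was highest in oligodendrocyte precursor-like nuclei, at 104 CPM (exact Poisson 95% interval 91.3 to 117), where 31.6% of nuclei held a UMI at a median depth of 3675 UMIs. In microglia-like nuclei, taken as a type that should lack it, 0.542% of nuclei held a UMI at a median depth of 1422.5. Precursor-like nuclei had 101 and 80.8 CPM with the inhibitor, 118 and 113 with GPLD1, and 113 with mutant GPLD1. Gpld1 passed the threshold in no class where it was tested. Alpl (ENSMUSG00000028766, GRCm38 chromosome 4, 137741733 to 137796384, minus strand), the gene of the inhibited phosphatase, had only 24, 13, 14, 39 and 23 UMIs over all nuclei (ALPL inhibitor 1 and 2, GPLD1 1 and 2, mutant GPLD1), which is 0.238 to 0.373 CPM, too few for a test in any class. Fibroblast-like nuclei held most Alpl per nucleus, at 160 CPM (89.3 to 263), with a UMI in 12 of 46 nuclei, against 0.0324% of oligodendrocyte-like nuclei. In endothelial-like nuclei neither gene had a UMI in 39 nuclei, which allows a share with a UMI of up to 9.03% (exact binomial 95% interval), and Cldn5, the main tight-junction protein of brain endothelium, was seen in 10 of them.

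GPLD1 against mutant GPLD1 compares both forms of the protein. In oligodendrocyte-like nuclei, 12 of 15 measured genes of the interferon response were lower with GPLD1, at a median log2 fold change of -0.32. The list of immediate early genes, which neurons switch on within minutes of activity, also holds later activity-induced genes such as Scg2. Its genes were lower in dentate granule neuron-like nuclei in 18 of 24 cases, at a median of -0.23. Of ribosomal protein genes, 73 of 83 were higher in subicular or cortical excitatory neuron-like nuclei, at a median of 0.24, which became -0.18 without GPLD1 2. These 3 lists passed camera with a preset correlation, and each had an adjusted p = 0.996 with an estimated correlation and also lost its call at equal total UMIs (adjusted p of 0.877, 0.33 and 0.372). With so few libraries the test with an estimated correlation could hardly pass, so it does not decide on these lists. Among single genes, Galntl6 alone passed the threshold, in Cajal-Retzius-like nuclei, and 1 nucleus supplied most of its counts.

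Galntl6 (ENSMUSG00000096914, GRCm38 chromosome 8, 57774052 to 58912640, minus strand) belongs to the family of enzymes that start O-linked glycosylation. It was higher with GPLD1 by 2.99 on the log2 scale (SE 0.52, n = 2 and 1, edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 0.000304). Its 595 UMIs in GPLD1 2 stood against 14 in GPLD1 1 and 33 with mutant GPLD1, and 369 of the 595 lay in 1 nucleus of 77. Without GPLD1 2 the log2 difference was -0.05, and without ALPL inhibitor 1 it was 2.98 but no longer passed (adjusted p = 1.0). This was the only call among 134576 tests in the 10 classes, where 3454 genes had an unadjusted p under 0.05 and DESeq2 called 0 (559 unadjusted). The count changed with every library that could be left out, at 24 and 16 calls without ALPL inhibitor 1 or 2, and at 115 and 225 without GPLD1 1 or 2. The mutant group has 1 library, which is assumed to vary as the others do.

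The interferon list passed camera with a preset correlation at an adjusted p of 0.00027, and its adjusted p = 0.996 with an estimated correlation. With each library but the mutant left out in turn it stayed at 0.0238 or below, while at equal total UMIs its median was -0.08 and the call ended. Ifi27l2a, an interferon-induced gene, had no UMI in either GPLD1 library and 12 with mutant GPLD1, which is at least 7.21-fold lower against a floor of 3 counts over the group, and with it at that bound the list's median stayed -0.32. The interferon-induced regulators Usp18 and Trim30a differed by -2.01 (SE 0.91) and -1.17 (SE 0.54), at levels below 4 CPM. None of these members passed on its own. In microglia-like nuclei the same list did not pass, yet Oasl2, an interferon-induced gene of the oligoadenylate synthetase family, had the smallest p of the genes named for that class. It stood at 6.71 and 6.18 CPM with GPLD1, 26.0 with mutant GPLD1, and 23.2 and 21.2 with the inhibitor, a log2 difference of -2.01 (SE 0.48, adjusted p = 1.0 by edgeR quasi-likelihood). Cxcl10, an interferon-induced chemokine, had 20 UMIs in 6 microglia-like nuclei of the mutant library and 1 UMI in the GPLD1 libraries together.

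The immediate early gene list in dentate granule neuron-like nuclei passed camera at an adjusted p of 0.0395, against an adjusted p = 0.996 with an estimated correlation, and stood at 0.127 without GPLD1 1. At equal total UMIs the adjusted p was 0.33, with a median of -0.18. Bdnf, a neurotrophin released with activity, was at 70.2 and 66.7 CPM with GPLD1 and 82.3 with mutant GPLD1 (log2 -0.27, SE 0.11), and the transcription factor genes Egr3 and Fosb differed by -0.45 (SE 0.21) and -1.56 (SE 0.72). Ribosomal protein genes passed at 0.0132, against an adjusted p = 0.996 with an estimated correlation, with Rps28 of the small subunit at 0.73 (SE 0.28). Without GPLD1 2 this list was lower instead, at a median of -0.18 and an adjusted p of 0.000857, and at equal total UMIs it stood at 0.14 and 0.372. The mix of clusters in this class differed, as 2 of its clusters held 460 and 329 of 1578 nuclei in GPLD1 2, 22 and 47 of 345 in GPLD1 1, and 111 and 91 of 748 with mutant GPLD1. With p adjusted over the list alone, 6 genes in 4 lists passed, against 0 of the list members adjusted over all genes. Genes with the smallest p in other classes did not pass. In CA1-like nuclei Gpc4, a GPI-anchored heparan sulfate proteoglycan, stood at 35.8 and 39.4 CPM with GPLD1 and 57.9 with mutant GPLD1 (log2 -0.62, SE 0.12), and Mlip differed by -0.53 (SE 0.11). Agbl1, a carboxypeptidase that trims tubulin, differed by -0.82 in inhibitory neuron-like nuclei (SE 0.15, adjusted p = 0.761 by edgeR quasi-likelihood), where Brd9, a part of a chromatin remodelling complex, differed by 0.67 (SE 0.15). Dentate Leng9 and Agrp, the latter a neuropeptide gene, were at 0.81 (SE 0.19) and 0.57 (SE 0.14), and in CA2 or CA3-like nuclei Prox2, a homeobox gene, was at 0.67 (SE 0.16).

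The ALPL inhibitor was compared with mutant GPLD1 and not with an untreated or vehicle group, so a difference can come from either treatment. In oligodendrocyte-like nuclei with the inhibitor, 18 of 20 genes of myelin and oligodendrocyte maturation were higher at a median log2 fold change of 0.26, as were 14 of 16 genes known from oligodendrocytes of aged or diseased brains, at a median of 0.43. In microglia-like nuclei, 22 of 25 genes of disease-associated microglia were higher, at a median of 0.38. Genes of cholesterol synthesis were lower in CA2 or CA3-like nuclei in 21 of 25 cases, and genes of GPI-anchored neuronal proteins in inhibitory neuron-like nuclei in 27 of 38, at a median of -0.12. These lists passed camera with a preset correlation only: each had an adjusted p = 0.964 with an estimated correlation, fry called 0, and no single gene passed with edgeR quasi-likelihood. The smallest unadjusted p with an estimated correlation was 0.059 over all lists. That test could hardly pass with so few libraries, so it does not decide on these lists. Without ALPL inhibitor 2 the myelin and microglia lists stood at 0.295 and 0.873, and without ALPL inhibitor 1 the cholesterol list stood at 0.123.

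The 16 lists past the threshold comprised 6 higher and 10 lower of 131 tests (36 at an unadjusted p under 0.05). With an estimated correlation 0 lists passed (0 also unadjusted), each at an adjusted p = 0.964 with an estimated correlation, and fry, which tests whether members move one way on balance, called 0 (3 unadjusted). Over all genes, edgeR quasi-likelihood called 0 of 134576 (3568 unadjusted), and DESeq2 called 1 (546 unadjusted). Calls numbered 576 without ALPL inhibitor 1, 3 without ALPL inhibitor 2, and 78 and 58 without GPLD1 1 or 2. The lone mutant library is again assumed to vary as the others do. With p adjusted over the list alone, 5 genes in 3 lists passed, against 0 over all genes.

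Among myelin genes (adjusted p = 0.00126 by camera, 0.295 without ALPL inhibitor 2), Mal, a proteolipid of compact myelin, was at 664 and 744 CPM with the inhibitor and 491 with mutant GPLD1. Ermn, a cytoskeletal protein of myelin, was at 357 and 443 CPM against 296, and Cldn11, the tight-junction protein between myelin layers, at 557 and 646 against 468. Genes of aged and diseased oligodendrocytes (adjusted p = 0.00199) stayed at 0.0161 or below with each library but the mutant left out in turn. Oligodendrocyte-like nuclei pool 4 clusters, and the cluster with C4b, a complement gene of that list, among its leading genes held 1017 of 4646 and 937 of 3055 of them with the inhibitor, 324 of 2113 and 899 of 5131 with GPLD1, and 716 of 3577 with mutant GPLD1. They included the tetraspanin Cd9 at 0.51 (SE 0.21), the secreted protease Klk6 at 0.98 (SE 0.45) and the prostaglandin D synthase Ptgds at 0.53 (SE 0.28). Glucocorticoid response genes also rose in these nuclei, with 14 of 16 higher at a median of 0.31 (adjusted p = 0.00199, and 0.38 without ALPL inhibitor 1). The metallothioneins Mt2 and Mt1 were at 0.79 (SE 0.36) and 0.59 (SE 0.28), and Hif3a, a transcription factor gene, was at 51.5 and 23.2 CPM against 16.1. Disease-associated microglia genes (adjusted p = 0.00199) stood at 0.873 without ALPL inhibitor 2, with Tyrobp, a signalling adaptor of microglial receptors, at 0.61 (SE 0.26), the oxidase subunit Cybb at 1.83 (SE 0.86) and the lysosomal protease Ctsd at 0.47 (SE 0.23). For all of these lists the adjusted p = 0.964 with an estimated correlation. Markers of neurons in oligodendrocyte-like nuclei, summed over 8 genes, were at 2240 and 1120 CPM with the inhibitor, 1670 and 2740 with GPLD1 and 2520 with mutant GPLD1, so that ALPL inhibitor 2 was lowest.

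In neurons, cholesterol synthesis genes were lower in 21 of 25 cases in CA2 or CA3-like nuclei (median -0.19, camera adjusted p = 0.00234, and 0.123 without ALPL inhibitor 1) and in 14 of 25 in CA1-like nuclei (median -0.17, 0.00706, and 0.224 without ALPL inhibitor 2). The pathway enzymes Fdft1 and Msmo1 stood at -0.38 (SE 0.16) in CA2 or CA3-like and -0.46 (SE 0.19) in CA1-like nuclei. The list of GPI-anchored neuronal proteins passed in inhibitory neuron-like nuclei (0.00199, at most 0.0436 with a library left out). Its members Gfra1, the receptor of a glial growth factor, Gpc6, a glypican, and Cdh13, a GPI-anchored cadherin, were at -0.49 (SE 0.13), -0.53 (SE 0.14) and -0.32 (SE 0.13), and 2 of its genes passed when adjusted over the list alone. In CA1-like nuclei this list had a median of -0.04 (0.0426, with 0.175 and 0.125 without ALPL inhibitor 1 or 2, and 0.0598 at equal total UMIs with the median still at -0.04). Immediate early genes rose in CA1-like nuclei (16 of 25 higher, median 0.21, 0.0217, with 0.137 without ALPL inhibitor 2 and 0.0598 at equal total UMIs, where the median was 0.19), where Junb, Egr1 and Arc were at 0.77 (SE 0.17), 0.94 (SE 0.23) and 0.67 (SE 0.20), and 2 genes passed when adjusted over the list alone. Each of these tests again had an adjusted p = 0.964 with an estimated correlation.

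Glycolysis and glucose uptake genes fell in 5 of 10 classes at adjusted p of 0.0217 to 0.0426 by camera, and their median was below 0 in all 10. These were inhibitory, CA1 and dentate granule neuron-like nuclei, precursor-like nuclei and microglia-like nuclei, with medians of -0.08, -0.10, -0.12, -0.32 and -0.35. Without ALPL inhibitor 2 these 5 calls ended, at medians of -0.09, -0.05, -0.12, -0.245 and -0.12. The medians of inhibitory and dentate nuclei thus did not shrink, while the others did. In microglia-like nuclei the call also ended without ALPL inhibitor 1, at a median of -0.475. Mitochondrially encoded genes fell in dentate granule neuron-like nuclei (8 of 11 lower, median -0.13, 0.0326, and 0.604 without ALPL inhibitor 2). Ribosomal protein genes rose in mossy cell-like nuclei (49 of 70 higher, median 0.20, 0.0412, with 0.484 without ALPL inhibitor 1 and 0.0502 without GPLD1 1). At equal total UMIs the glycolysis lists of inhibitory, dentate and precursor-like nuclei had medians of -0.12, -0.10 and -0.46 and no longer passed (0.104, 0.104 and 0.287). The mitochondrial list then stood at -0.06 (0.176) and the ribosomal list at 0.34 (0.0733). For these lists too the adjusted p = 0.964 with an estimated correlation. Whether RNA from outside the nuclei adds to them was not tested. Of single genes in the smaller neuronal classes, Ncam2, a neural adhesion molecule, had the smallest p in mossy cell-like nuclei at 113 and 56.9 CPM against 195 (log2 -1.16, SE 0.23, adjusted p = 0.134 by edgeR quasi-likelihood). It was also at -1.68 (SE 0.42, adjusted p = 0.198) in Cajal-Retzius-like nuclei, beside the protocadherin Pcdh7 at -2.35 (SE 0.56, adjusted p = 0.184). CA1-like Mid1, a ubiquitin ligase gene, was at -0.64 (SE 0.14), and AC149090.1 at 0.78 (SE 0.16), and neither passed with edgeR quasi-likelihood, while AC149090.1 was the only gene called by DESeq2.

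GPLD1 against the ALPL inhibitor compares both treatments directly, with 2 libraries on each side. Its inhibitor libraries are those already compared with mutant GPLD1. A list that changed there can therefore show the opposite sign here without any effect of GPLD1. The GPLD1 libraries are shared with the first comparison as well, where the same sign can recur. In oligodendrocyte-like nuclei, 13 of 16 genes of aged and diseased oligodendrocytes were lower at a median log2 fold change of -0.62, and in microglia-like nuclei 23 of 25 disease-associated genes were lower at a median of -0.49. Interferon response genes were lower in both classes, at medians of -0.37 and -0.40, and 20 of 24 immediate early genes were lower in dentate granule neuron-like nuclei, at a median of -0.37. All of these lists passed camera with a preset correlation, and each had an adjusted p = 0.99 with an estimated correlation. As above, the latter test could hardly pass with so few libraries. Without ALPL inhibitor 2 the microglia list of disease-associated genes stood at 0.0989 and that of interferon genes at 0.152 (0.136 without GPLD1 2), and the dentate list stood at 0.874 without ALPL inhibitor 1.

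For the aged and diseased oligodendrocyte list the camera adjusted p was 9.93e-13, and it stayed at 1.91e-05 or below with each library left out in turn, against an adjusted p = 0.99 with an estimated correlation. The shift between clusters given for the inhibitor against mutant GPLD1 runs along with this change, and no test was made within a cluster. Klk6 was at 8.47 and 9.21 CPM with GPLD1 and 16 and 33.6 with the inhibitor, with 12.4 in the mutant library (log2 -1.45, SE 0.37). Serpina3n, a protease inhibitor induced in reactive glia, was at 14.1 and 13.3 CPM against 21.8 and 46.1 (log2 -1.30, SE 0.35). Cd9 was at 155 and 192 CPM against 261 and 254, and Socs3, an inhibitor of cytokine signalling, at 1.06 and 1.41 against 2.93 and 6.95. The disease-associated microglia list had an adjusted p of 5.35e-12 and 0.0989 without ALPL inhibitor 2, and again an adjusted p = 0.99 with an estimated correlation. Its members Cd9 (116 and 131 CPM against 195 and 195) and Gpnmb, a glycoprotein of lipid-laden phagocytes (1.68 and 2.32 against 9.30 and 14.6), showed no overlap between the groups. With 2 libraries on each side this is common without any effect, and members were named for their small p. Lgals3, a galectin of phagocytes, had 1 and 1 UMIs with GPLD1 against 6 and 30, and lipoprotein lipase Lpl was at 6.71 and 8.5 CPM against 13.3 and 34.4. No member of these lists passed on its own, with an adjusted p of 0.999 or above by edgeR quasi-likelihood. Neuronal markers summed over 8 genes were at 1650 and 2920 CPM with GPLD1 and 2420 and 1130 with the inhibitor in microglia-like nuclei, so that ALPL inhibitor 2 was again lowest.

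**Figure D2:**
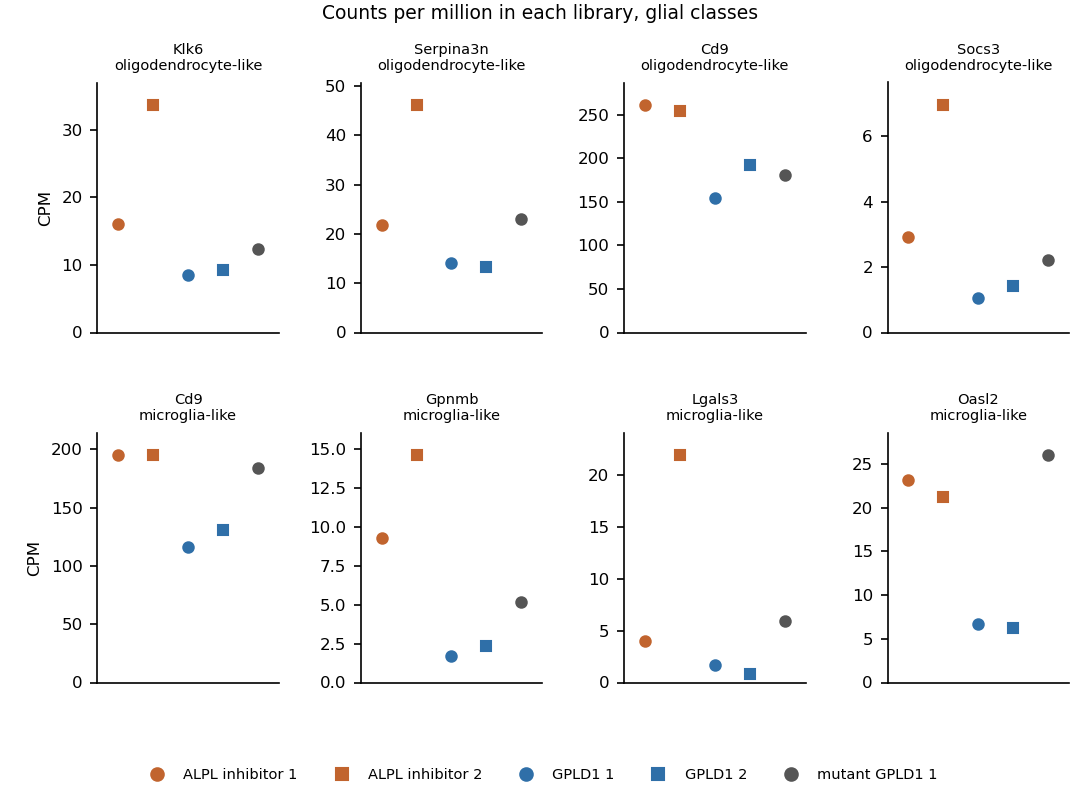
CPM per library (TMM-scaled, linear axis from 0) of Klk6, Serpina3n, Cd9 and Socs3 in oligodendrocyte-like nuclei and of Cd9, Gpnmb, Lgals3 and Oasl2 in microglia-like nuclei, with 1 point per library. Both GPLD1 libraries lie below both ALPL inhibitor libraries for each of these genes, and none passed an adjusted p of 0.05. The genes were named for small p in these same data, so this order is no separate evidence.

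Interferon genes passed in microglia-like nuclei (16 of 19 lower, camera adjusted p = 1.71e-06, with 0.152 without ALPL inhibitor 2 and 0.136 without GPLD1 2) and in oligodendrocyte-like nuclei (13 of 15 lower, 0.000225). In the latter the call held with each library left out, at 0.023 or below, yet at equal total UMIs the median was 0.06 and the adjusted p 0.432. Both had an adjusted p = 0.99 with an estimated correlation. Microglial Oasl2 was at 6.71 and 6.18 CPM against 23.2 and 21.2 (log2 -1.79, SE 0.43) and Trim30a at 163 and 126 against 205 and 221. Antigen presentation by MHC class I fell in microglia-like nuclei (14 of 18 lower, median -0.33, 0.00165, and 0.662 without ALPL inhibitor 2) and in oligodendrocyte-like nuclei (8 of 12 lower, median -0.10, 0.0278), where it stood at 0.433 without ALPL inhibitor 2, at a median of 0.03 without GPLD1 1, and at a median of -0.11 (0.19) at equal total UMIs. Complement genes fell in microglia-like nuclei (5 of 8 lower, median -0.18, 0.0477), with 0.648 without ALPL inhibitor 2 and 0.461 without GPLD1 2. Glucocorticoid response genes fell in oligodendrocyte-like nuclei (12 of 16 lower, median -0.28, 0.000533, and 0.556 without ALPL inhibitor 1), with Hif3a at 19.4 and 8.06 CPM against 51.5 and 23.2. Myelin genes fell there as well (16 of 20 lower, median -0.13, 0.00681, with 0.934 without ALPL inhibitor 2 and 0.625 without GPLD1 2), with Cldn11 at 442 and 418 CPM against 557 and 646. For all of these lists the adjusted p = 0.99 with an estimated correlation. Mmp12, the macrophage elastase, had no UMI in microglia-like nuclei of either GPLD1 library and 20 and 13 with the inhibitor, at least 7.18-fold lower, while the peptide transporter gene Slc15a2 was at 36.9 and 34.0 CPM against 8.64 and 14.6. Neither of these passed, with an adjusted p of 0.999 for both by edgeR quasi-likelihood.

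In neurons, the immediate early list of dentate granule neuron-like nuclei had a camera adjusted p of 2.01e-05, and without ALPL inhibitor 1 its median was 0.03 (0.874). Bdnf was at 70.2 and 66.7 CPM with GPLD1 and 95 and 91.5 with the inhibitor (log2 -0.45, SE 0.09), and Scg2, a secretory granule protein, and Nr4a2, a nuclear receptor, were at -0.40 (SE 0.16) and -0.41 (SE 0.18). The same list fell in CA1-like nuclei (17 of 25 lower, median -0.12, 0.00681, with 0.209 without ALPL inhibitor 2 and 0.847 without GPLD1 1), with the nuclear receptor Nr4a1 at 23.8 and 29.1 CPM against 42.3 and 35.8, and Dusp6, a phosphatase that curbs ERK signalling, at 7.09 and 6.62 against 10.6 and 9.54. GPI-anchored neuronal proteins rose in inhibitory neuron-like nuclei (29 of 38 higher, median 0.11, 0.00383, with 0.124 without ALPL inhibitor 2 and 0.0821 without GPLD1 1), with Lypd6, a GPI-anchored modulator of nicotinic receptors, at 70.6 and 65.5 CPM against 46.8 and 50.0, and Cdh13 at 505 and 447 against 370 and 379. Cholesterol synthesis genes rose in CA2 or CA3-like nuclei (21 of 25 higher, median 0.16, camera adjusted p = 0.00553), and without ALPL inhibitor 1 the call ended while the median was 0.18. The pathway enzyme Nsdhl of this list was at 0.59 (SE 0.22). Every one of these tests had an adjusted p = 0.99 with an estimated correlation. Adjusted over the list alone, 8 genes in 7 lists passed in this comparison, against 0 list members over all genes. Further genes with the smallest p of their class were Nnat, a proteolipid of developing neurons, and Tox, a nuclear factor, at 0.55 (SE 0.11) and -0.42 (SE 0.09) in CA1-like nuclei, and the potassium channel subunit Kcnv1 at -0.99 (SE 0.17, adjusted p = 0.182 by edgeR quasi-likelihood) in CA2 or CA3-like nuclei.

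Energy and ribosome lists rose with GPLD1 against the inhibitor, and most of them turned on GPLD1 2. That library also had the highest Ttr, a choroid plexus gene, in 10 of 10 tested classes. Whether RNA from outside the nuclei adds to these lists was not tested. Oxidative phosphorylation genes were higher in microglia-like nuclei (75 of 91, median 0.26, camera adjusted p = 0.00681) and oligodendrocyte-like nuclei (75 of 93, median 0.15, 0.0495), and without GPLD1 2 both were lower, at medians of -0.27 and -0.27. Glycolysis genes passed in CA1-like, subicular or cortical, oligodendrocyte-like and precursor-like nuclei at 0.00901, 0.0125, 0.0155 and 0.0241, with medians of 0.16, 0.17, 0.25 and 0.27 that became -0.07, 0.12, -0.09 and -0.22 without GPLD1 2. Ribosomal protein genes passed in precursor-like nuclei (61 of 78 higher, median 0.25, 0.0159) and had a median of -0.44 without GPLD1 2. Hypoxia response genes passed in CA1-like nuclei (12 of 13 higher, median 0.16, camera adjusted p = 0.0159). Without GPLD1 2 that call ended, while the median was 0.17. Without ALPL inhibitor 2 these calls ended too. Medians were then 0.12 and 0.12 for oxidative phosphorylation, 0.055, 0.19, 0.14 and 0.35 for glycolysis, 0.11 for ribosomal proteins and 0.09 for hypoxia. Glycolysis thus did not shrink in subicular or cortical and precursor-like nuclei, while the other medians did. Without ALPL inhibitor 1 the calls of glycolysis in subicular or cortical nuclei and of oxidative phosphorylation in oligodendrocyte-like nuclei ended, at medians of 0.12 and 0.17. Oxidative phosphorylation in oligodendrocyte-like nuclei had a camera adjusted p of 0.0505 without the mutant library, at a median of 0.15. At equal total UMIs oxidative phosphorylation had medians of 0.21 and 0.13 in microglia-like and oligodendrocyte-like nuclei (0.0512 and 0.147), glycolysis 0.17 and 0.34 in oligodendrocyte-like and precursor-like nuclei (0.0848 and 0.452), and ribosomal proteins 0.15 (0.495), so these calls ended too. Of subicular or cortical nuclei, the same 2 clusters that held 460 and 329 of 1578 in GPLD1 2 held 177 and 79 of 685 and 113 and 64 of 410 with the inhibitor. With an estimated correlation the adjusted p = 0.99 for each, as for all 21 lists of this comparison (10 higher, 11 lower, 33 of 131 at an unadjusted p under 0.05), of which 0 were called (2 unadjusted), and fry also called 0 (6 unadjusted).

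**Figure D3:**
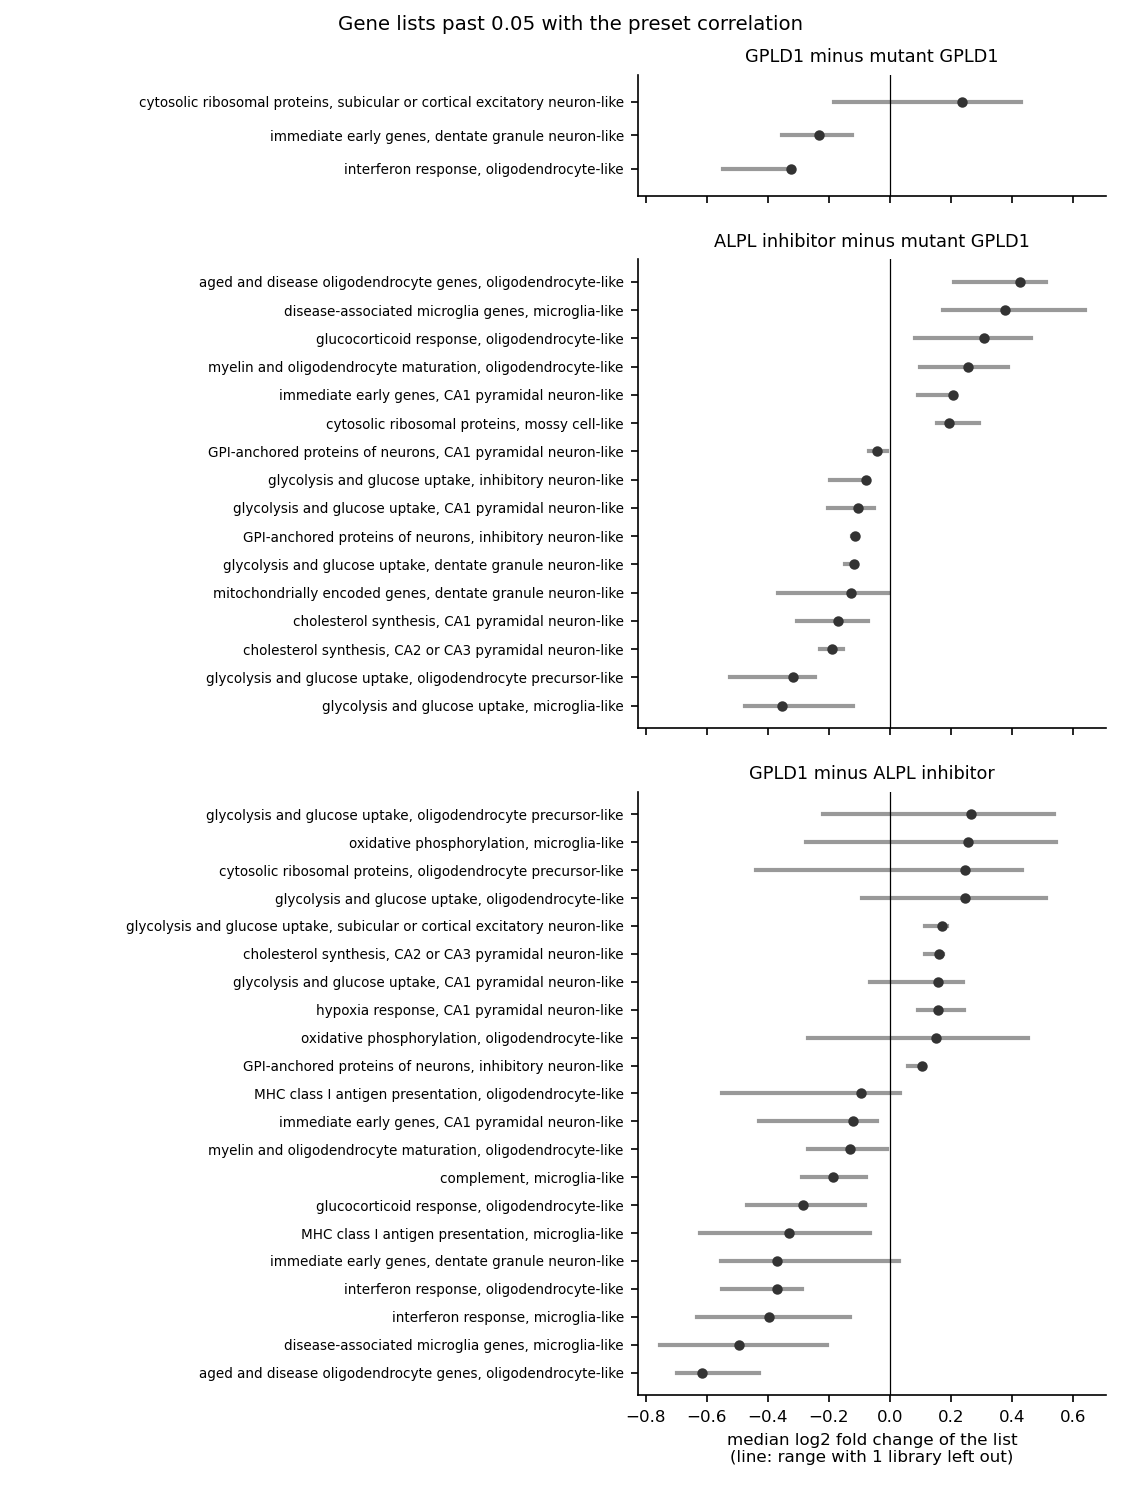
Median log2 fold change of each gene list that passed an adjusted p of 0.05 by camera with a preset correlation, in 3 panels for the 3 comparisons (3, 16 and 21 lists), with lines for the range when 1 library is left out. The list of aged and diseased oligodendrocyte genes lies at 0.43 for the inhibitor against mutant GPLD1 and at -0.62 for GPLD1 against the inhibitor.

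Single genes past the threshold for GPLD1 against the inhibitor numbered 5, of which 4 were higher and 1 lower (134576 tests, edgeR quasi-likelihood, Benjamini-Hochberg), while 4401 had an unadjusted p under 0.05 and DESeq2 called 0 (758 unadjusted). Galntl6 was higher in Cajal-Retzius-like nuclei by 3.43 (SE 0.43, n = 2 and 2, adjusted p = 1.69e-09) and stood at 0.40 without GPLD1 2. As given above, 1 nucleus held most but not all of its UMIs in that library, and no fit without that nucleus was made. In mossy cell-like nuclei Lrrtm4 (ENSMUSG00000052581, GRCm38 chromosome 6, 80018877 to 80810143, plus strand), a synaptic adhesion protein, was at 327 and 446 CPM with GPLD1 and 249 and 146 with the inhibitor (log2 0.96, SE 0.19, adjusted p = 0.0462). Erbb4 (ENSMUSG00000062209, GRCm38 chromosome 1, 68032186 to 69108059, minus strand), a neuregulin receptor, was lower there at 3.04 and 14.2 CPM against 71.9 and 21.7 (log2 -2.22, SE 0.43, adjusted p = 0.0462), and 57 of its 74 UMIs in ALPL inhibitor 1 lay in 1 nucleus. Ttr (ENSMUSG00000061808, GRCm38 chromosome 18, 20665280 to 20674321, plus strand), the thyroid hormone carrier made by the choroid plexus, was higher in precursor-like nuclei by 3.22 (SE 0.54, adjusted p = 1.88e-05). Its UMIs were 1 and 52 with GPLD1 and 0 and 6 with the inhibitor, and without GPLD1 2 the log2 difference was -0.21. The fifth gene, a predicted transcript, was also higher in precursor-like nuclei. The count was 112 and 55 without ALPL inhibitor 1 or 2, 110 and 237 without GPLD1 1 or 2, and 0 without the mutant library, and none of the calls held with DESeq2. Without ALPL inhibitor 1 the calls of Galntl6, Erbb4 and Ttr ended, at log2 differences of 2.975, -1.04 and 2.23. The call of Lrrtm4 ended without ALPL inhibitor 2 and without GPLD1 2, at 0.65 and 0.70. Without the mutant library the adjusted p by edgeR quasi-likelihood was 0.532 for Lrrtm4 and Erbb4 and 0.999 for Galntl6, while the log2 differences there were 0.97, -2.21 and 3.42.

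**Figure D4:**
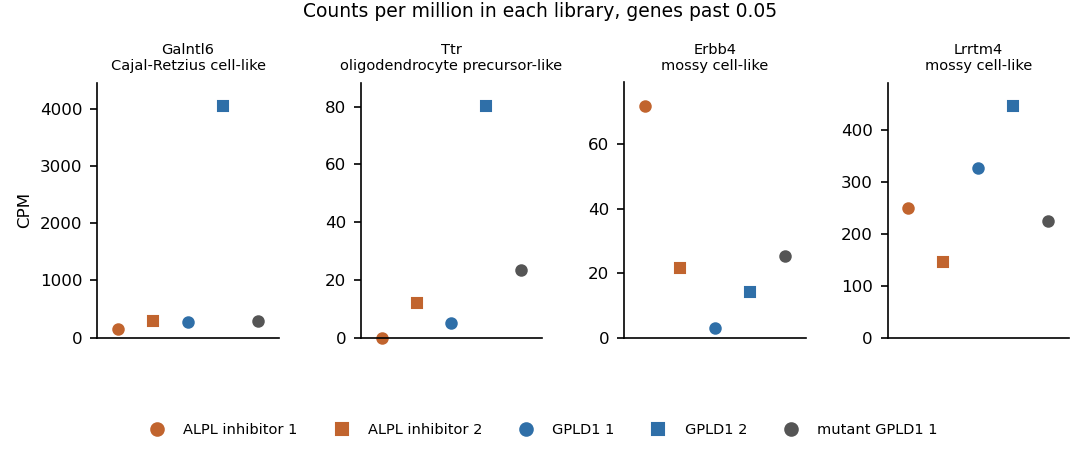
CPM per library (TMM-scaled, linear axis from 0) of Galntl6 in Cajal-Retzius-like nuclei, Ttr in precursor-like nuclei, and Erbb4 and Lrrtm4 in mossy cell-like nuclei, with 1 point per library. Galntl6 reaches 4060 CPM in GPLD1 2 against 150 to 286 in the other libraries, and Ttr reaches 80.3 against 0 to 23.4.

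Both comparisons against mutant GPLD1 share 1 library, so their fold changes correlate even without any effect. Across genes, which are not independent replicates, Pearson correlations of both sets of fold changes were 0.496 in mossy cell-like to 0.655 in oligodendrocyte-like nuclei. Simulated unchanged groups against that library gave medians of 0.560 to 0.647 over 100 draws per class, and in 0 of 10 classes did the observed value exceed the 95th percentile of its simulations. Covariances lay below the simulated median in all 10 classes, for example 0.0969 against 0.1206 in oligodendrocyte-like nuclei. A split of the mutant library was not possible. In these simulations the shared library alone gave correlations of this size, so no effect shared by both treatments can be read from them.

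Several lists fixed in advance passed in no class and no comparison. The closest was that of synaptic receptors and scaffolds, whose medians lay between -0.10 and 0.03 in 12 tests (smallest adjusted p = 0.067 by camera, 1 unadjusted). Enzymes of GPI anchor synthesis and remodelling had medians of -0.22 to 0.25 in 30 tests (0.142, 1 unadjusted), circadian clock genes -0.50 to 0.20 in 30 tests (0.148, 2 unadjusted), and heat shock genes -0.22 to 0.26 in 30 tests (0.148, 1 unadjusted). Homeostatic microglia genes had medians of 0.01 to 0.14 in 3 tests (0.23, 1 unadjusted), and neurogenesis genes -0.05 to 0.01 in 3 tests of dentate granule neuron-like nuclei (0.56, 0 unadjusted), with fry calling 0 for each of them.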

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

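Shares of unnamed clusters, thinning to equal total UMIs and leaving out a library were planned. Tests of border macrophage markers, of AC149090.1 and of Ttr, and the use of the planned tests to weigh explanations, were chosen after the result was seen. Among nuclei left without a class name, 4 clusters had, in 1 treated library each, a share whose exact binomial 95% interval lay wholly above that of the mutant library, which is the rule for being listed here. A cluster led by Ebf2, Sema3a, Ebf3 and Postn held 0.688% of ALPL inhibitor 1 against 0.0439% of mutant GPLD1. A second, led by Cpa6, Zic4, Zic1 and Zfp521, held 2.24% of ALPL inhibitor 1 against 0.386%. A cluster with microglial leading genes and high doublet scores held 0.0888% of GPLD1 2 and 0 nuclei of mutant GPLD1, and a cluster with granule neuron genes and high doublet scores held 0.239% of GPLD1 2 against 0.0351%. The rule did not list shares below the mutant library. A cluster led by Bsg and Ttr, counted with its endothelial-like part, held 3.84% of mutant GPLD1 and 1.51% to 2.5% of the treated libraries. Another, with Gpc3 and Cped1 among its leading genes, held 2.01% and 0.446% to 1.23%. In both, the interval of the mutant library lay above that of every treated library. A cluster made mostly of 1 library may be that library's dissection or its doublets rather than a cell type, and this was not tested beyond the value of 2.24%; no biological explanation was tested.

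Lower disease-associated genes in microglia-like nuclei with GPLD1 than with the ALPL inhibitor form the first pattern weighed. A difference in total UMIs of the class does not account for it. At equal totals the list kept an adjusted p of 1.65e-08 by camera with a preset correlation and a median log2 fold change of -0.39. Thinning did not equalise the depth per nucleus, so an effect of that depth stays open. Median UMIs over all nuclei were 3532 and 2483 with the inhibitor and 5187 and 4194 with GPLD1. With an estimated correlation the list's adjusted p was 0.99, and fry called 0 lists in this comparison. Border macrophages mixed into the class remain open, because only 3 of their markers were measured there and their median of 0.123 had quartiles of -0.37 and 1.00. A deviation of 1 library is in line with the result, as the adjusted p rose to 0.0989 and the median shrank from -0.49 to -0.20 without ALPL inhibitor 2. An effect of the treatments stays open and untested beyond these libraries.

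The gene AC149090.1 (ENSMUSG00000095041, GRCm38 scaffold JH584304.1, 52190 to 59690, minus strand) was lowest in the mutant library in 10 of 10 tested classes, with losses of 57.2 CPM in oligodendrocyte-like to 387 CPM in mossy cell-like nuclei. A shift of the whole mutant library in the normalization is argued against, since 1 factor moves every gene alike, while at most 0.602% of genes with similar UMIs differed as far in the same direction in any class. Free RNA that differs between libraries is argued against too, because the loss differed 6.77-fold between classes. It was 57.2 CPM in oligodendrocyte-like and 326 CPM in microglia-like nuclei, which had similar median depths of 1427 and 1422.5 UMIs, where free RNA would add about equally. A strain or animal difference of the 1 mutant library, reads shared with related sequences, and an effect of the treatments could each still be the reason and cannot be separated with 1 library.

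Ttr, higher in precursor-like nuclei with GPLD1 than with the inhibitor, was highest in GPLD1 2 in 10 of 10 tested classes. It reached 274 CPM in oligodendrocyte-like, 260 CPM in microglia-like and 27.1 CPM in CA1-like nuclei of that library, against 10.1, 1.61 and 0.422 CPM in GPLD1 1. Free RNA of choroid plexus in that library is a candidate source, since a change within precursors would not need these 10 classes to share it. In these classes GPLD1 1 lay below both inhibitor libraries (27.7 and 35.7, 13.9 and 39.7, and 1.63 and 3.12 CPM) and the mutant library (78.0, 59.6 and 6.36 CPM). In precursor-like nuclei its 4.72 CPM lay between the 0 and 11.5 CPM of the inhibitor libraries. High Ttr thus went with GPLD1 2 and not with both GPLD1 libraries. Free RNA itself was not measured.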

How the results depend on the processing

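The crossed replicate block was chosen after seeing the data, and all other alternatives were planned. Under each of them the cause was not tested where a value moved, except where fewer libraries, genes or UMIs entered by construction. No value could be given for endothelial-like nuclei. Counts of changed genes for GPLD1 against mutant GPLD1 (1) were 2 with RLE, 0 with DESeq2, 96 without the filter on low counts, 27 with only the groups compared, 2 at 1000 UMIs, 2 with doublets kept, 4 at resolution 2, 0 after thinning and 16 to 225 with a library left out. For the inhibitor against mutant GPLD1 (0) they were 1 with DESeq2, 105 without the filter, 42 with only the groups compared, 12 with doublets kept, 37 at resolution 2 and 3 to 576 with a library left out. For GPLD1 against the inhibitor (5) they were 0 with DESeq2, 127 without the filter, 0 with only the groups compared, 13 with doublets kept, 14 at resolution 2, 0 after thinning, 3 with at least 30 nuclei and 0 to 237 with a library left out. The extremes came without ALPL inhibitor 2 (16), GPLD1 2 (225 and 237), ALPL inhibitor 2 (3), ALPL inhibitor 1 (576) and the mutant library (0). Lists called (3, 16 and 21) were 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with fry, where 3, 3 and 6 had an unadjusted p under 0.05. They were 7 with only the groups compared and 0 after thinning for GPLD1 against mutant GPLD1, 10 after thinning for the inhibitor against mutant GPLD1, and 12 without the filter for GPLD1 against the inhibitor. With a library left out they ranged from 5 to 37, 7 to 24 and 8 to 51, with 37 without GPLD1 2, 51 without GPLD1 1, and 7 and 8 without ALPL inhibitor 2. Shares gave 1 call for the inhibitor against mutant GPLD1 with TMM over classes, and otherwise 0, with 0 to 0 for a library left out. Classes correlated beyond the shared control (0) were 1 with RLE, 1 at resolution 2 and 2 after thinning.

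Of the 6 gene calls, 6 ended with DESeq2 and 6 after thinning, 5 ended without ALPL inhibitor 1 and 5 were lost or changed sign without GPLD1 2 (2 of them with a changed sign), 4 ended without the mutant library, 4 with only the groups compared, 2 with RLE, 2 with doublets kept, 1 without the filter and 1 without ALPL inhibitor 2, and 6 held without GPLD1 1. Without the mutant library, as with only the groups compared, no call was left for GPLD1 against the inhibitor, and Ttr had no value there. Ranges with a library left out crossed 0 for Galntl6 against mutant GPLD1 (-0.049 to 3.84) and Ttr (-0.21 to 7.74), both lowest without GPLD1 2. Of the 40 list calls, 40 held with RLE, 23 after thinning, 30 without ALPL inhibitor 1, 13 without ALPL inhibitor 2, 35 without GPLD1 1 and 28 without GPLD1 2. List medians that changed sign without GPLD1 2 ranged from -0.18 to 0.43 for ribosomal proteins in subicular or cortical nuclei against mutant GPLD1. Against the inhibitor, those that did so without GPLD1 2 ranged from -0.44 to 0.44 for ribosomal proteins in precursors, from -0.065 to 0.24, -0.22 to 0.54 and -0.092 to 0.51 for glycolysis in CA1, precursor and oligodendrocyte nuclei, and from -0.27 to 0.55 and -0.27 to 0.45 for oxidative phosphorylation in microglia and oligodendrocytes. Immediate early genes in dentate nuclei ranged from -0.55 to 0.032 (highest without ALPL inhibitor 1) and MHC class I in oligodendrocytes from -0.55 to 0.034 (highest without GPLD1 1). Myelin genes ranged from -0.27 to -0.009, where the direction of camera turned without ALPL inhibitor 2. The interferon list in oligodendrocytes ranged from -0.55 to -0.29 and had a median of 0.057 after thinning. Of 74 named genes short of the threshold, none changed direction, and 20 passed without the filter and 16 without GPLD1 2. Thinning lowers depth by construction.

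Libraries with the same replicate number gave no sign of pairing, as their deviations correlated at -0.025 to -0.312 across genes. However, the deeper library was number 1 with the inhibitor (87131545 kept UMIs against 54658267) and number 2 with GPLD1 (104635294 against 50487827). Depth may enter these correlations, so they cannot exclude a pairing by number. The crossed block below also separates the deeper from the shallower libraries. With the replicate block, genes called were 7, 7 and 40 and lists 16, 25 and 19 in the order of comparisons above, and shares 0 in each, while 8 of the 40 list calls and 3 of the 6 gene calls ended. With the crossed block, which pairs ALPL inhibitor 1 with GPLD1 2 and ALPL inhibitor 2 with GPLD1 1 and was chosen after seeing the data, they were 3, 20 and 79 genes, 26, 23 and 20 lists and 0 shares, and 12 of the 40 list calls and 2 of the 6 gene calls ended. Galntl6 against mutant GPLD1 was lost under both, with an adjusted p of 0.999 for the replicate block and 0.188 for the crossed block.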

Other observations

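Following Cxcl10 across libraries was chosen after the result was seen, while the tests of lists were planned. Genes of aged and diseased oligodendrocytes were higher with the inhibitor than with mutant GPLD1 and lower with GPLD1 than with the inhibitor, by camera with a preset correlation. Both comparisons contain the same inhibitor libraries, so opposite signs arise without any effect, and no value without an effect was computed for them. The adjusted p = 0.964 and 0.99 with an estimated correlation, and fry called neither. With a library left out the medians ranged from 0.21 to 0.51 and from -0.70 to -0.43 and both calls held, but the mutant library could not be left out of the comparison with it. For GPLD1 against mutant GPLD1 the list had a median of -0.08 and did not pass (adjusted p = 0.184 by camera), although its unadjusted p was under 0.05. Which group carries the difference is therefore open.

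Gpld1 was measured in the brain cells themselves. Precursor-like nuclei (104 CPM) and dentate granule neuron-like nuclei (33.5 CPM, a UMI in 22.3% of nuclei) had the highest levels of the tested classes, and microglia-like nuclei had 3.58 CPM. Cxcl10 UMIs lay in 6 microglia-like nuclei of the mutant library, with 10 UMIs in 1 of them, and in 1 nucleus each of ALPL inhibitor 2 and GPLD1 2.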
